A study of Sus scrofa with 12 samples.

How the data were processed

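Total RNA was measured in 12 stented coronary artery segments of 6 pigs, 4 segments from 2 pigs for each of 3 stent types, collected 28 days after implantation. Per the labels' protocols, tissue was dissected by hand from the stent, RNA was extracted with an RNeasy kit, and amplified cDNA was fragmented and labelled with biotin. The deposited values are log2 signals made by the authors with Affymetrix Expression Console 5.0 and MAS5, per the submitters' processing notes. The scale and the base of the logarithm were read from the values, since 2 to the power of the value has a trimmed mean, with 2% left out at each end, between 500.15 and 500.17 on all 12 arrays. The target value of the scaling, the treatment of low signals and any detection calls are not given in the sources used here. Between 41 and 1153 probe sets per array are listed at 0, which marks a floor and not an absence of RNA.

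The file holds 24123 probe sets. After 124 control probe sets were left out, the 30% with the lowest mean over all arrays were removed, which left 16799; 5 of these are reporter gene controls, none of which was called. Names came from the platform's annotation, in which 10069 probe sets have 1 gene symbol, 198 have several and 13732 have none. Only probe sets with 1 symbol were named, and 5793 genes were tested in this way. A gene with several probe sets was represented by the one with the highest mean over all 12 arrays. The values are already log2, so the pseudocount was 0 and no further normalization was applied.

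Stent types were compared with limma 3.58.1 in R 4.3.3 (statmod 1.5.0), with stent type as the fixed term, all 12 arrays in one model, the pig as a random block by duplicateCorrelation, and eBayes with a variance trend. The consensus correlation within pigs was -0.0322, so the block made the tests more liberal than arrays taken as independent. The probe sets changed, SES minus BMS, probe sets changed, ZES minus SES, and probe sets changed, any stent group (F test), were 114, 12 and 58 with the block against 89, 6 and 29 without it. Tests were two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05, and intervals are at 95%. An F test covered the 3 types together. LAD and RCA were compared with the pig as a fixed block. Gene lists were tested with cameraPR at a preset correlation of 0.01 on 1 probe set per gene, adjusted over the 33 of 34 lists with at least 5 measured genes. The lists cover cell types of the vessel wall and of blood, matrix, inflammation, drug targets and general cell functions, and the list of eosinophil and mast cell genes had too few measured members. Beside it, camera with a correlation estimated on means per pig and fry, which asks whether the genes of a list move one way without comparing them with other genes, were run. With the correlation estimated on means per pig, which is meant wherever an estimated correlation is named for a comparison of stents, no list passed in any comparison. This test ran on means per pig and not on the 12 arrays, so it differs from the preset test in more than the correlation. The estimated correlation was -0.023 for T and NK cell markers and -0.029 for leukocyte adhesion. It was 0.63 for smooth muscle contractile markers and 0.80 for cytosolic ribosomal proteins. With one estimated on the arrays taken as independent, which was added after seeing the data, 2 lists passed for SES against BMS, cytokines and chemokines and T and NK cell markers, and 0 in each of the other comparisons. Fry with the pig block called 5 lists for SES against BMS, 0 for ZES against BMS and 1 for ZES against SES. The 5 were cytokines and chemokines, T and NK cell markers, calcification and bone matrix, immediate early and stress genes, and coagulation and fibrinolysis. For ZES against SES it was cytokines and chemokines. Smooth muscle contractile markers gave adjusted p = 0.0510 with fry for SES against BMS.

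Named genes are, in each comparison, the 8 that rose most and the 8 that fell most among those past the threshold; where fewer than 5 passed, the 10 with the smallest p; in each list that shifted or held at least 3 members past the threshold, up to 4 members with the smallest adjusted p; and a fixed panel of vessel wall, inflammation and drug target genes. Of the panel, MYH11, COL1A1, CD68, MKI67 and MTOR had no probe set with that symbol alone, and SELE was removed by the filter. The design, the lists, the rule for named genes and the alternatives, apart from those named as later choices, were fixed before the data were examined.

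The background level of an array was the 95th percentile of its 59 control probe sets for sequences that were not spiked in. Where a gene was not above it on any array of the dimmer group, its fold is given as at least the brighter group's mean over the dimmer group's mean of, per array, the higher of the background and the gene's own signal. The number of arrays and pigs limits the precision.

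The procedure was tested on simulated arrays with the means and spreads of the 16799 probe sets and 200 changed between SES and BMS, in 5 draws. Of 2-, 4-, 8- and 16-fold changes, 4%, 32%, 58.4% and 74.8% were recovered without a correlation within pigs, and 3.2%, 26.8%, 57.2% and 68.8% with a correlation of 0.3. Of the calls 10.3% and 7.29% were false, more than the threshold of 0.05 allows. A list with a planted shift was found in 5 of 5 draws. Probe sets were drawn independently of each other, so these draws cannot show how the list test behaves where the genes of a list are correlated. For ZES against BMS, with no change planted, 0.2 and 0 probe sets were called on average.

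Alternatives were means per pig, arrays as independent, quantile normalization, median centring, the 25th percentile of all linear values (20.6) as a pseudocount, no filter or 50% left out, robust eBayes, eBayes without the trend, array weights, artery as a covariate, a minimum change of 2-fold, an adjusted p under 0.01, only the arrays of the groups compared, other list tests, and each array and each pig left out. The artery covariate set RCA against the other arteries, and each stent type had equal numbers of both. It could change the spread but not the differences between stent types, and it did not adjust for the number of LAD segments. An alternative without a pseudocount is void, since none was added to the log2 values. When arrays were left out the correlation within pigs was estimated on 5000 probe sets. The spike-in level and the GAPDH 3' minus 5' difference as covariates, the removal of the pair of arrays with a 28S ribosomal RNA control above 14 (BMS 1 and ZES 2) and median centring for lists were chosen after seeing the data. Both covariates separate every SES array from every BMS array, and the GAPDH difference also every SES array from every ZES array. A call that ended with such a covariate therefore does not show that the control, and not the stent type, was its source. Median centring moved the median of all probe sets to 0.17 for SES minus BMS and to 0.14 for ZES minus BMS, from -0.020 and -0.014.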

Results

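Gene expression was measured in coronary artery tissue of Yorkshire farm pigs 28 days after angioplasty and stent implantation. The study compared 3 stent types, a bare metal stent (BMS), a sirolimus-eluting stent (SES) and a zotarolimus-eluting stent (ZES); the series title speaks of overlapping stents and of inflammation and extracellular matrix genes. Sirolimus inhibits the mTOR kinase and slows the growth of smooth muscle cells, and zotarolimus is a sirolimus analog with a tetrazole ring in place of a hydroxyl group. The doses on the stents were not given in the sources used here. Each stent type was represented by 4 artery segments from 2 pigs, so that 12 arrays came from 6 pigs. In 5 pigs the segments were from the right coronary artery (RCA) and the left anterior descending artery (LAD), and in 1 pig with SES they were from the RCA and the left circumflex artery. Segments are named here by stent type and a number from 1 to 4, with 1 and 2 from one pig and 3 and 4 from the other. Because the animals number only 2 per group, the p-values rest mainly on the spread between segments.

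The Affymetrix porcine array gave log2 signals for 24123 probe sets, of which 16799 were tested. Between 61.0% and 74.5% of probe sets lay above the background level of their array. That level was 5.51 ± 0.31 with BMS, 4.72 ± 0.54 with SES and 4.72 ± 0.41 with ZES (log2, mean ± SD). Exact permutation gave p = 0.0857 for SES against BMS and p = 0.0286 for ZES against BMS (adjusted p = 0.154 and 0.103). A gene therefore had to be brighter on BMS arrays to count as above background. Probe sets listed at 0 averaged 172 with BMS, 656 with SES and 725 with ZES. The arrays were on one scale, with a trimmed mean linear signal between 500.15 and 500.17, and correlated with each other at 0.735 to 0.906. Their controls differed between the stent groups. The spike-in controls, added at hybridisation, read 16.30 ± 0.38 with BMS, 15.09 ± 0.43 with SES and 15.30 ± 0.58 with ZES (log2, mean ± SD, n = 4 arrays each). The GAPDH control, read near the 3' end of the transcript minus near its 5' end, was 4.16 ± 0.50 with BMS, 2.71 ± 0.35 with SES and 3.66 ± 0.19 with ZES. Both controls were lower on every SES array than on any BMS array (exact permutation p = 0.0286, two-sided, the smallest that 70 arrangements allow, and adjusted p = 0.103 over 18 such tests). The GAPDH difference was also lower on every SES array than on any ZES array, with ZES 0.95 above SES at the same p and adjusted p. The EF1A control, 3' minus 5', was lower on every SES array than on any BMS array (difference -0.95, exact permutation p = 0.0286, two-sided) but did not separate ZES from SES (0.67, exact permutation p = 0.171). The actin control, 3' minus middle, was 2.44 ± 0.19 with BMS, 2.28 ± 0.23 with SES and 2.35 ± 0.18 with ZES.

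**Figure D1:**
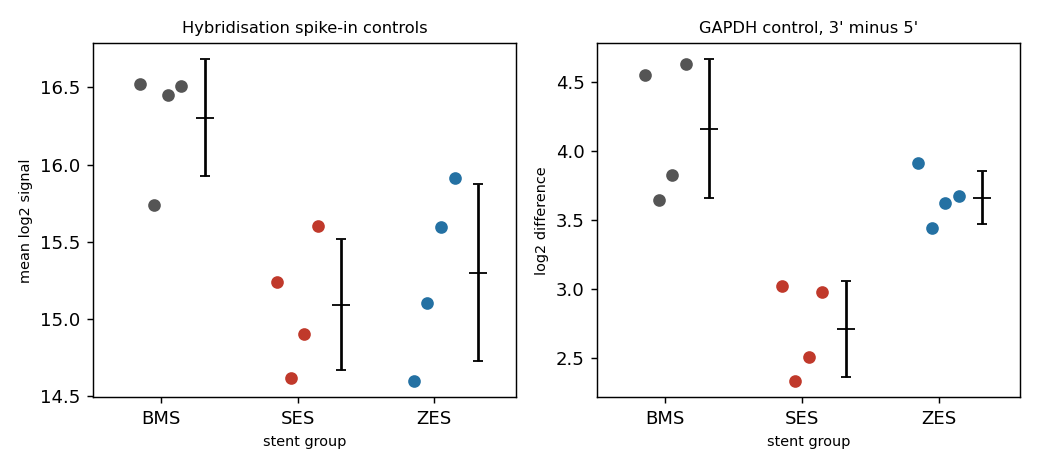
Control signals of the 12 arrays by stent group (left, mean log2 signal of the spike-in controls; right, log2 difference between the 3' and 5' GAPDH control probe sets). Points are arrays, and bars are the mean ± SD of 4 arrays; the SES arrays lie below the BMS arrays on both axes, at 15.09 against 16.30 and at 2.71 against 4.16.

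The comparison of SES with BMS asks what the sirolimus-eluting stent adds to stenting itself. As lists, cytokine and chemokine genes and T and NK cell markers were higher around SES, and contractile smooth muscle markers were lower. Of their members 5, 2 and 0 passed singly, and with an estimated correlation the list tests gave adjusted p = 0.379, adjusted p = 0.379 and adjusted p = 0.445. Monocyte and macrophage markers (median -0.058, adjusted p = 0.695) and B and plasma cell markers (median 0.85, adjusted p = 0.310) did not pass as lists. CXCL13, which attracts B cells, rose by 4.74 ± 0.68 (log2, estimate ± SE), from 6.38 ± 1.35 with BMS to 11.13 ± 0.81 with SES (mean ± SD, n = 4; adjusted p = 0.00725), with 1 BMS array at background. CCL5 and CCL2, which attract T cells and monocytes, rose 10.4-fold and 4.73-fold (adjusted p = 0.00549 for both). FOS, an immediate early transcription factor, rose by 4.64 ± 0.78 (adjusted p = 0.0167), with 1 BMS array at background. CD3E, a chain of the T cell receptor complex, was not above background on any of the 4 BMS arrays and was at least 4.33-fold higher with SES (adjusted p = 0.0172).

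Among the 29 measured cytokine and chemokine genes, 25 had a positive difference, with a median of 1.44, and the list shifted up (adjusted p = 4.96e-13). Members that rose were CCL2, CCL5, CXCL13, CCL24 (by 3.47 ± 0.59) and LTB (by 3.24, named after its value was seen), and 10 rose when adjusted over the list alone. The 15 T and NK cell markers shifted up with a median of 1.72 (adjusted p = 7.09e-06). Their mean with BMS, 5.11, lay below the mean BMS background level of 5.51, so the size of this shift is uncertain. Lists were not tested with a pseudocount. CD3E and the adaptor SH2D1A, at 3.72 ± 0.75 with 3 BMS arrays at background, rose, and 7 markers rose when adjusted over the list alone. Immediate early and stress genes shifted up with a median of 1.02 over 22 genes (adjusted p = 2.86e-06), where FOS and IER3 (by 3.77 ± 0.58) rose and 7 rose when adjusted over the list alone. Of 13 genes for MHC class II and antigen presentation, which display peptides to helper T cells, 11 were positive (median 0.69, adjusted p = 6.49e-05). SLA-DRB1 rose 4.44-fold and SLA-DQA1 3.55-fold, and 4 rose when adjusted over the list alone. With an estimated correlation, the list tests gave adjusted p = 0.379 for cytokines and for T and NK cell markers and adjusted p = 0.445 for the immediate early and MHC class II lists. With the correlation estimated on arrays taken as independent, a choice made after seeing the data, cytokines and chemokines and T and NK cell markers each gave adjusted p = 0.0328, and no other list passed. The median of cytokines and chemokines was 0.88 with the spike-in level and 0.73 with the GAPDH difference as a covariate. With the spike-in level it was 0.98 for T and NK cell markers and 0.38 for MHC class II and antigen presentation.

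The 27 smooth muscle contractile markers were all lower with SES than with BMS, with a median of -1.69 (adjusted p = 3.11e-16, and adjusted p = 0.445 with an estimated correlation). No marker passed over all probe sets tested in limma, where 2408 probe sets had an unadjusted p under 0.05, and 20 fell when adjusted over the list alone. CNN1, calponin, had a difference of -3.15 ± 0.81 (adjusted p = 0.0804) and ACTA2, smooth muscle actin, one of -1.52 ± 0.44 (adjusted p = 0.110). The list means were 9.19, 9.41 and 9.49 on SES 1 to 3 and 11.28 on SES 4, against 11.21 to 11.93 on the BMS arrays. The 17 cardiomyocyte markers, of heart muscle, had list means of 6.04 to 6.18 on SES 1 to 3 and 8.54 on SES 4, against 6.16 to 8.19 on the BMS arrays, and did not pass as a list (median -0.84, adjusted p = 0.0741). The median of the smooth muscle contractile markers was -0.61 with the spike-in level as a covariate (list test adjusted p = 0.00586) and -1.10 when all probe sets of a gene were averaged. The 56 genes for cytosolic ribosomal proteins were all lower as well, with a median of -0.50 (adjusted p = 3.05e-10, and adjusted p = 0.601 with an estimated correlation), but this median turned to 0.020 with quantile normalization and to 0.33 with the spike-in level as a covariate. It was -0.31 with median centring.

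**Figure D2:**
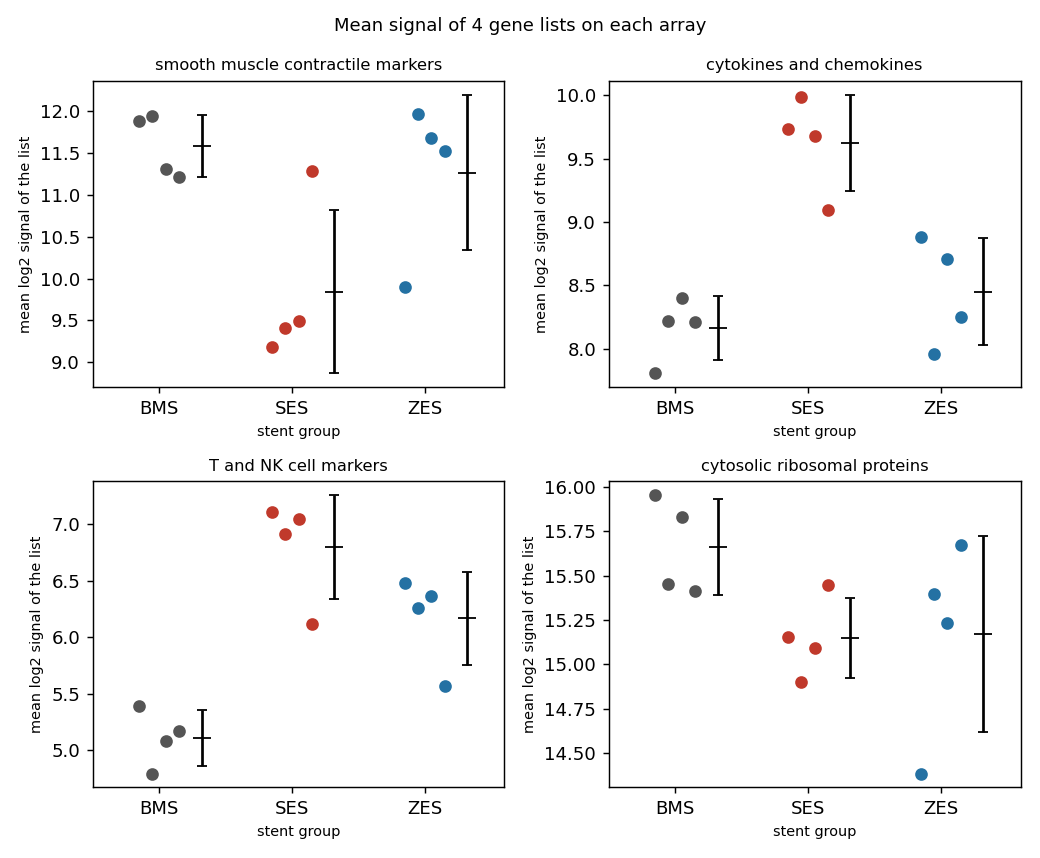
Mean log2 signal of 4 gene lists on each of the 12 arrays, by stent group. Points are arrays, and bars are the mean ± SD of 4 arrays; cytokine means were 9.62 ± 0.38 with SES against 8.16 ± 0.25 with BMS, while the SES minus BMS median of the cytosolic ribosomal proteins turned to 0.020 under quantile normalization.

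Matrix genes, named in the series title, went both ways. The 35 proteoglycans and matrix glycoproteins had a median of -0.27 (adjusted p = 0.0190) and included LAMB2, a laminin chain of basement membranes, which fell by 2.43 on the log2 scale (SE 0.48). Fibronectin, FN1, was 1.53 ± 0.40 higher (adjusted p = 0.0825), while its second probe set had a difference of -0.81 (adjusted p = 0.607). The 12 calcification and bone matrix genes had a median of -1.15 (adjusted p = 0.000814), with 1 higher and 7 lower when adjusted over the list alone, among them the osteoclast protease CTSK at -1.17 ± 0.27 (adjusted p = 0.0569). Fibroblast and adventitial markers had a median of -0.57 (adjusted p = 0.0108). TIMP1, an inhibitor of matrix proteases, rose 2.69-fold (adjusted p = 0.0336), while the 23 proteases and inhibitors as a list did not shift (adjusted p = 0.989). COL4A2, a basement membrane collagen named after its value was seen, fell by 2.04 on the log2 scale, and the 12 collagens as a list did not shift (adjusted p = 0.268). With an estimated correlation the lists that shifted gave adjusted p = 0.472 for proteoglycans and adjusted p = 0.445 for the calcification and fibroblast lists. For proteoglycans and matrix glycoproteins the call ended without BMS 1 (median -0.079, adjusted p = 0.0622), without SES 3 (median -0.17, adjusted p = 0.183) and without both arrays of high 28S ribosomal RNA signal, BMS 1 and ZES 2 (median -0.081, adjusted p = 0.114). It also ended with quantile normalization (median -0.22, adjusted p = 0.0529), with the spike-in level (median -0.012, adjusted p = 0.793) and with the GAPDH difference as a covariate (median 0.077, adjusted p = 0.749). The median was -0.57 without SES 4 and -0.073 with median centring. With the spike-in and GAPDH covariates the calls ended for calcification and bone matrix (median -0.35, adjusted p = 0.225 and median -0.55, adjusted p = 0.486) and for fibroblast and adventitial markers (median -0.23, adjusted p = 0.565 and median -0.61, adjusted p = 0.0644). The median of the latter was -0.37 without BMS 1, -0.37 without the arrays of high 28S signal and -0.38 with median centring.

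Further lists shifted up with SES. Coagulation and fibrinolysis genes had a median of 1.13 (adjusted p = 0.00246), where tissue factor, F3, had a difference of 4.76 ± 1.31 (adjusted p = 0.0978) with 2 BMS arrays at background. Glycolysis and hypoxia genes had a median of 0.54 (adjusted p = 0.00850), leukocyte adhesion genes one of 0.53 (adjusted p = 0.0206) and cell cycle genes one of 0.53 (adjusted p = 0.00758). ICAM1, which binds leukocyte integrins, rose 5.92-fold (adjusted p = 0.0401). Interferon response genes shifted down with a median of -0.85 (adjusted p = 0.00122), although GBP1 of this list had a difference of 1.31 ± 0.46 (adjusted p = 0.186). These lists gave adjusted p = 0.445 for coagulation and leukocyte adhesion, adjusted p = 0.542 for glycolysis and interferon and adjusted p = 0.676 for cell cycle with an estimated correlation. The call of cell cycle and proliferation ended without BMS 1 (median 0.24, adjusted p = 0.238), BMS 2 (median 0.33, adjusted p = 0.115) or both arrays of high 28S signal (median 0.25, adjusted p = 0.175), with a median of 0.86 without BMS 3. That of leukocyte adhesion ended without BMS 3 (adjusted p = 0.112), SES 2 (adjusted p = 0.0533) or SES 4 (adjusted p = 0.0584) and with all probe sets of a gene averaged (adjusted p = 0.0602). The spike-in level as a covariate ended the calls of leukocyte adhesion (median 0.58, adjusted p = 0.711), coagulation and fibrinolysis (median 0.63, adjusted p = 0.653), interferon response (median -0.13, adjusted p = 0.302) and glycolysis and hypoxia (median 0.25, adjusted p = 0.371). The GAPDH difference ended that of glycolysis and hypoxia (median 0.44, adjusted p = 0.0532) and moved the medians of coagulation and fibrinolysis to 0.60 and of interferon response to -1.37.

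Other named genes also had large changes. PNP, purine nucleoside phosphorylase, rose by 4.76 ± 0.96, PARM1 by 4.47 ± 0.90 and CDA, cytidine deaminase, by 4.29 ± 0.82, where PNP and PARM1 were at background on 2 BMS arrays each and CDA on 1. BTG2, an inhibitor of proliferation, and UPK1B, a uroplakin, were not above background on any of the 4 BMS arrays and were at least 3.69-fold and at least 1.61-fold higher with SES. With a pseudocount the log2 differences of CD3E, BTG2 and UPK1B were 2.85, 2.75 and 1.83, against fitted values of 4.90, 4.62 and 4.32 without one. Among the genes that fell were ASPA (-3.12 ± 0.62, with 1 SES array at background), COASY, coenzyme A synthase (-2.96 ± 0.48), GJA4, a gap junction protein of arterial endothelium (-2.87 ± 0.61), the water channel AQP1 (-2.63 ± 0.55), the ubiquitin ligase RNF128 (-2.49 ± 0.46), the ADP receptor P2RY12 (-2.47 ± 0.48) and ASL, argininosuccinate lyase (-2.47 ± 0.49). Of the fixed panel, CCL2, CD3E and TIMP1 rose. CXCL8 (3.36 ± 1.35), IL1B (2.18 ± 0.88), TNC (-2.55 ± 0.97), VWF (1.96 ± 0.89), MMP9 (1.71 ± 0.87), VCAM1 (0.89 ± 0.39), CD163 (0.85 ± 0.45), COL3A1 (0.68 ± 0.58), SPP1 (0.58 ± 0.62) and PECAM1 (0.17 ± 0.37) did not pass. VWF was at background on 2 BMS arrays and 1 SES array, and CXCL8, IL1B and COL3A1 on 1 BMS array each. The drug-binding immunophilins FKBP1A (0.63 ± 0.27) and FKBP5 (-0.12 ± 0.28) did not pass either. The second probe sets of PECAM1 (-1.03) and FKBP5 (0.085) had the opposite sign.

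**Figure D3:**
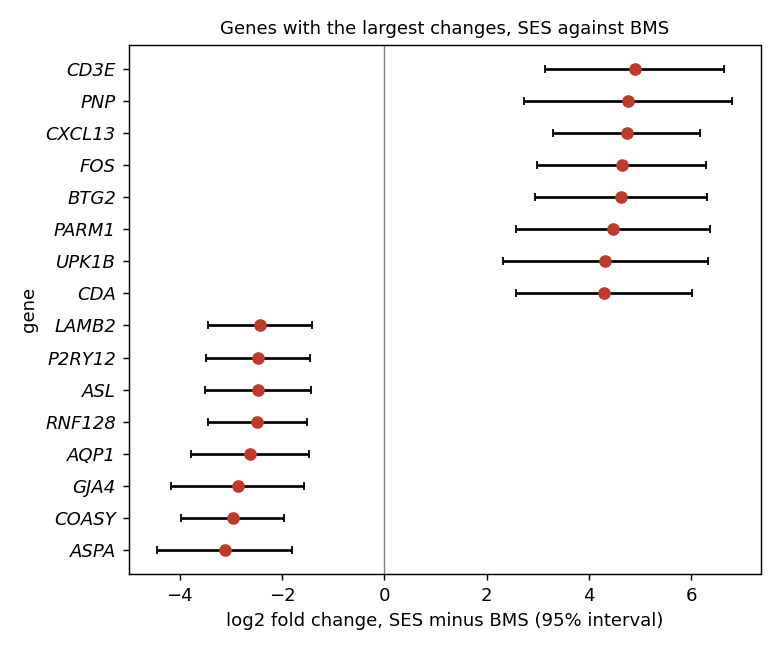
Log2 fold change, SES minus BMS, of the 8 genes that rose most and the 8 that fell most among those past the threshold. Points are limma estimates from 12 arrays and bars are 95% intervals; for CD3E, BTG2 and UPK1B the BMS signal was not above background, so that their folds are bounded only from below, at 4.33, 3.69 and 1.61.

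In all, 114 probe sets passed between SES and BMS at an adjusted p under 0.05, 83 higher and 31 lower, and they include 52 named genes, 39 higher and 13 lower. Of the fixed lists 14 shifted, 8 up and 6 down, and 18 list members changed. The number of probe sets changed, SES minus BMS, was 64 on means per pig, 19 without a variance trend, 196 with a pseudocount, 183 without the filter, 678 with array weights and 178 from the 8 arrays alone. It was 26 without the arrays of high 28S signal, 8 at an adjusted p under 0.01 and 0 with the spike-in level or 0 with the GAPDH difference as a covariate in limma (2408 at an unadjusted p under 0.05 without a covariate). Both covariates were lower on every SES array than on any BMS array, so these counts of 0 cannot tell the covariate from the stent type. The number was 0 without SES 3, so that each call of a single gene ended there. It was 11 without SES 1, 18 without SES 2, 40 without BMS 1, 64 without BMS 2, 190 without BMS 4, 205 without ZES 4 and 420 without SES 4. Leaving out whole pigs gave 1 without SES 1 and 2, 365 without ZES 1 and 2, 487 without BMS 3 and 4 and 76 without BMS 1 and 2.

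The comparison of ZES with BMS asks the same of the zotarolimus-eluting stent. No single gene passed. T cell, neutrophil and leukocyte adhesion lists shifted up and interferon and smooth muscle lists shifted down at the preset correlation, but with an estimated correlation the T cell and adhesion lists gave adjusted p = 0.786 and the others adjusted p = 0.808. The smooth muscle contractile markers turned from a median of -0.28 to 0.26 without ZES 1, and their list mean differed by -0.32 (exact permutation p = 0.771, two-sided). CD3E was at least 2.29-fold higher with ZES, with a signal of 6.71 ± 0.81 (mean ± SD, n = 4) where none of the 4 BMS arrays was above background (adjusted p = 0.256). The endothelial and platelet adhesion protein VWF had a difference of 3.69 ± 0.89 (adjusted p = 0.340) with 2 BMS arrays at background, and PDPN, podoplanin, one of 2.37 ± 0.48 (adjusted p = 0.219).

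The 15 T and NK cell markers shifted up with a median of 1.05 (adjusted p = 0.00430), and 5 rose when adjusted over the list alone. Here too the BMS mean of the list lay below the mean BMS background level, so the size of the shift is uncertain. Neutrophil markers had a median of 2.39 over 7 genes (adjusted p = 0.0416), among them MMP9 (2.39 ± 0.87) and S100A8 (5.14 ± 1.58), the pair that rose when adjusted over the list alone. This was not particular to ZES. For SES minus BMS the list had a median of 1.71 without passing (adjusted p = 0.146), and 3 members rose when adjusted over the list alone. S100A8 differed there by 5.20 ± 1.58. For ZES minus SES the list median was -0.066 (adjusted p = 0.784). S100A8 read 11.39 to 11.77 on ZES 1, 3 and 4 and 3.97 on ZES 2, and it was at background on that array and on 3 BMS arrays. Leukocyte adhesion genes (median 0.58, adjusted p = 0.0220) and cell cycle genes (median 0.47, adjusted p = 0.0110) shifted up. Interferon response genes shifted down (median -0.51, adjusted p = 0.0110), and 3 of them, IFIT1, IFIT2 and XAF1, fell when adjusted over the list alone. The smooth muscle contractile markers shifted down with a median of -0.28 (adjusted p = 0.0416). The cytosolic ribosomal proteins had a median of -0.51 (adjusted p = 4.38e-15), which was -0.031 with quantile normalization, turned to 0.19 with the spike-in level as a covariate and was -0.23 without ZES 1. None of these list calls held with an estimated correlation, which gave adjusted p = 0.786 for T and NK cell markers and leukocyte adhesion and adjusted p = 0.808 for the other lists. For T and NK cell markers and leukocyte adhesion that correlation was -0.023 and -0.029, not above the preset 0.01. A higher correlation between their genes was therefore not what ended these calls, and the test also ran on means per pig.

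Most of these list calls depended on single arrays. The call of cell cycle and proliferation ended without BMS 1 (median 0.11, adjusted p = 0.617), BMS 2 (median 0.31, adjusted p = 0.244) or ZES 1 (median 0.23, adjusted p = 0.284), with medians of 0.76 without BMS 3 and 0.86 without ZES 2. That of interferon response ended without BMS 1 (median -0.45, adjusted p = 0.111), BMS 2 (median -0.32, adjusted p = 0.115) or ZES 1 (median -0.28, adjusted p = 0.185) and had a median of -0.80 without BMS 4. That of leukocyte adhesion ended without BMS 1 (median 0.79, adjusted p = 0.0811), BMS 3 (median 0.46, adjusted p = 0.128) or ZES 1 (median 0.31, adjusted p = 0.185). The call of neutrophil markers ended without BMS 1 (median 2.01, adjusted p = 0.146), BMS 2 (median 1.98, adjusted p = 0.121) or BMS 3 (median 2.44, adjusted p = 0.0965), and equally without ZES 1 (median 1.60, adjusted p = 0.185), ZES 3 (median 2.16, adjusted p = 0.150) or ZES 4 (median 1.86, adjusted p = 0.143). It also ended with quantile normalization (adjusted p = 0.0542) and with median centring (median 2.55). For smooth muscle contractile markers the direction turned without ZES 1 (median 0.26) and with the spike-in covariate (median 0.49, adjusted p = 0.153). The call ended without BMS 1 (median -0.082, adjusted p = 0.229), without BMS 2 (median -0.098, adjusted p = 0.244) and with quantile normalization (median -0.19, adjusted p = 0.163). The median was -0.12 with median centring, -0.42 with the GAPDH covariate, -0.45 without the arrays of high 28S signal, -0.42 without BMS 4 and -0.45 without ZES 2. Averaging all probe sets of a gene ended the calls of leukocyte adhesion (adjusted p = 0.0757), neutrophil markers (adjusted p = 0.0545) and smooth muscle contractile markers (adjusted p = 0.502). The median of T and NK cell markers was 0.53 without BMS 4. With the spike-in covariate none of the lists passed, at median 0.50, adjusted p = 0.449 for T and NK cell markers.

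The genes with the smallest p, none of which passed, were LOC100152327 (4.18 ± 0.76), LOC396781 (4.01 ± 0.73), PLAC8 (-3.26 ± 0.57), all at adjusted p = 0.116, PDPN, CD3E, IKBKG (2.22 ± 0.49), LOC100621559 (2.71 ± 0.57), MT-2B (-1.61 ± 0.35), STIM2 (1.89 ± 0.42) and NOTCH4, which was at least 2.95-fold higher than the background of the BMS arrays. Panel genes with the largest differences after CD3E and VWF were MMP9 and IL1B (-2.15 ± 0.88, with 2 ZES arrays and 1 BMS array at background), whose second probe set differed by 0.048. CCL2 was 1.01 ± 0.30 and TIMP1 0.85 ± 0.29 higher, and ACTA2 was at -0.82 ± 0.44. FN1 (0.61 ± 0.40), CD163 (0.63 ± 0.45), VCAM1 (0.71 ± 0.39), PECAM1 (0.46 ± 0.37), COL3A1 (0.22 ± 0.58), SPP1 (0.097 ± 0.62), TNC (-0.20 ± 0.97), CXCL8 (-0.34 ± 1.35), FKBP1A (-0.027 ± 0.27) and FKBP5 (0.093 ± 0.28) did not pass.

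With limma 0 probe sets passed between ZES and BMS, and 1510 had an unadjusted p under 0.05, where 840 are expected by chance. No list member passed, and 7 lists shifted, 4 up and 3 down, against 4 lists, 3 up and 1 down, with quantile normalization, 3 up and 4 down with median centring, 0 with the spike-in level as a covariate and 0 with fry. The number of probe sets changed, ZES minus BMS, became 3 without the filter, 4 without BMS 3, 2 without BMS 4 and 4 without ZES 1. Leaving out a pig gave 13 and 79 for the BMS pigs and 5 and 12 for the ZES pigs. The number of gene lists shifted, ZES minus BMS, was 2 without BMS 1, 2 without ZES 1, 4 without BMS 2 and 4 with all probe sets of a gene averaged.

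The direct comparison of ZES with SES sets the stents with the 2 related drugs side by side, in different pigs and at doses not given in the sources used here. As lists, smooth muscle contractile markers were higher with ZES, and cytokine and chemokine genes and immediate early genes were lower. All 3 lists gave adjusted p = 0.513 with an estimated correlation, and CXCL13 was the only member of them to pass. The GAPDH control difference was likewise higher on every ZES array, at 3.44 or more, than on any SES array, at 3.02 or less (exact permutation p = 0.0286, two-sided, and adjusted p = 0.103). CXCL13, at 11.13 ± 0.81 with SES (mean ± SD, n = 4), fell, with a difference of -5.13, a 95% interval from -6.57 to -3.69 and adjusted p = 0.00712. Its second probe set differed by -2.62 (adjusted p = 0.270). RPUSD1, a pseudouridine synthase family member, was 2.78 higher (interval 2.05 to 3.51, adjusted p = 0.00604). Also higher were LOC100152327, by 4.29 ± 0.76, and COASY, by 2.67 ± 0.48. PLAC8 (-3.34 ± 0.57), the arrestin family gene ARRDC4 (-2.70 ± 0.42) and IDH1, cytosolic isocitrate dehydrogenase (-1.88 ± 0.34), fell.

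Of the 27 smooth muscle contractile markers 25 were higher with ZES, with a median of 1.39 (adjusted p = 1.97e-12, and adjusted p = 0.513 with an estimated correlation), and 14 rose when adjusted over the list alone. CNN1 differed by 2.95 ± 0.81 and KCNMB1, a potassium channel subunit, by 2.45 ± 0.67. The list mean was 9.90 on ZES 1 and 11.52 to 11.95 on the other ZES arrays. Of 29 cytokines and chemokines 26 were lower with ZES (median -0.86, adjusted p = 5.58e-10), where CXCL13 fell, and 9 fell and 1 rose when adjusted over the list alone. IL1B differed by -4.32 ± 0.88 (adjusted p = 0.0660, with 2 ZES arrays at background) and CCL5 by -2.45 ± 0.46 (adjusted p = 0.0544). Immediate early and stress genes had a median of -1.15 (adjusted p = 2.17e-06), with FOS at -2.81 ± 0.78, and 11 fell and 1 rose when adjusted over the list alone. MHC class II genes (median -0.35, adjusted p = 0.00348), mitochondrial respiration genes (-0.27, adjusted p = 0.00348) and coagulation genes (-0.55, adjusted p = 0.0125) shifted down, and proteoglycans shifted up (0.35, adjusted p = 0.0142). Adjusted p = 0.666 for mitochondrial respiration and adjusted p = 0.513 for the other lists were obtained with an estimated correlation.

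Several of these list calls ended when an array was left out. That of MHC class II and antigen presentation ended without ZES 2 (median -0.28, adjusted p = 0.0541), without both arrays of high 28S signal (median -0.28, adjusted p = 0.0680) and with the GAPDH covariate (median -0.56, adjusted p = 0.0725). Its median was -0.21 without SES 3, -0.66 without ZES 1 and -0.53 with all probe sets of a gene averaged. That of coagulation and fibrinolysis ended without SES 2 (median -0.70, adjusted p = 0.0618), without ZES 4 (median -0.61, adjusted p = 0.121) and with the GAPDH covariate (median -0.82, adjusted p = 0.0725). For mitochondrial respiration it ended with the GAPDH covariate (median -0.073, adjusted p = 0.548), and the median was -0.18 without SES 1 and -0.44 without SES 4. For proteoglycans and matrix glycoproteins it ended without SES 3 (median 0.26, adjusted p = 0.219), ZES 3 (median 0.39, adjusted p = 0.0664) or ZES 4 (median 0.20, adjusted p = 0.0778) and with the spike-in covariate (median 0.32, adjusted p = 0.0644), and the direction turned with the GAPDH covariate (median -0.050, adjusted p = 0.943).

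For the panel the intervals of the difference between ZES and SES were wide. They ran from -2.67 to 0.83 for CD3E, -1.85 to -0.61 for CCL2, -0.22 to 1.62 for ACTA2, -1.20 to 0.038 for TIMP1, -1.76 to -0.074 for FN1 (whose second probe set differed by 0.90), -1.79 to 0.83 for SPP1, 0.29 to 4.40 for TNC, -1.16 to 2.52 for MMP9 and -0.14 to 3.61 for VWF. The largest panel differences were those of IL1B, with an interval from -6.18 to -2.46, and CXCL8, at -3.70 with an interval from -6.56 to -0.84 and 1 ZES array at background. VCAM1 differed by -0.19 ± 0.39. The intervals were -0.49 to 1.08 for PECAM1, -1.18 to 0.74 for CD163 and -1.70 to 0.76 for COL3A1. For FKBP1A the interval was -1.22 to -0.085 and for FKBP5 -0.38 to 0.80. None of these panel genes passed after adjustment, and with intervals of this width equal expression is not shown for any of them.

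Between ZES and SES 12 probe sets passed, 5 higher and 7 lower, with 7 named genes, and 7 lists shifted, 2 up and 5 down. The number of probe sets changed, ZES minus SES, was 4 on means per pig, 6 with arrays as independent, 6 with quantile normalization, 6 with median centring, 46 with a pseudocount, 48 without the filter, and 0 without a variance trend (1686 at an unadjusted p under 0.05 in limma with the trend). It was 307 with array weights, 26 with artery as a covariate, 5 with the spike-in covariate, 0 with the GAPDH covariate, 4 without the arrays of high 28S signal, 5 from the 8 arrays alone and 2 at an adjusted p under 0.01. It was 0 without SES 3, where each call of a single gene ended. It was 3 without SES 1, 2 without SES 2, 161 without SES 4, and 35 without BMS 1. It was 32 without BMS 4, 33 without ZES 1, 3 without ZES 2, 2 without ZES 3 and 21 without ZES 4. By pig it was 61 and 68 for BMS, 1 and 61 for SES, and 12 and 50 for ZES. The number of gene lists shifted, ZES minus SES, was 11 without SES 4, 11 without ZES 1 and 3 with the GAPDH covariate.

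An F test over the 3 stent types called 58 probe sets. The number of probe sets changed, any stent group (F test), was 29 with arrays as independent, 5 without a variance trend, 104 with a pseudocount, 108 without the filter, and 630 with array weights. It was 10 without the arrays of high 28S signal, 3 at an adjusted p under 0.01, 2 with the spike-in covariate and 0 with the GAPDH covariate, where 2257 probe sets had an unadjusted p under 0.05 in limma without a covariate. Single arrays moved it to 0 without SES 3, 5 without SES 2, 7 without SES 1, 26 without BMS 2, 27 without ZES 2, 33 without BMS 1, 98 without ZES 4, 103 without ZES 1, 130 without BMS 4 and 265 without SES 4. Pigs left out moved it to between 1 and 344.

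The differences of SES and of ZES from BMS correlated across probe sets at r = 0.588, where probe sets are not independent replicates and both differences share the 4 BMS arrays. Simulated arrays without any effect gave 0.501 on average, and the covariance was 0.544 against 0.309 in the simulation, a difference of 0.235. With the BMS arrays split by pig, so that no array was shared, r was 0.0923 and 0.118. Among probe sets at an unadjusted p under 0.05, 387 were higher in both comparisons, against 58.1 for independent lists and 83 in 1 simulated draw without effects, and 181 were lower in both, against 50.2 and 93. The real lists held 1231 and 793 probe sets higher and 1177 and 717 lower with SES and ZES. The sizes of the simulated lists are not given, and the simulation drew probe sets independently of each other. The shared counts therefore do not show effects common to both drug stents.

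Artery was tested within pigs. With limma 0 probe sets passed between LAD and RCA, where 1140 had an unadjusted p under 0.05 and the smallest adjusted p was 0.728.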

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

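The tests of explanations and of other splits in this part were written down after the results were seen; quantile normalization and leaving out single arrays had been planned, and only their use as tests came later. Within groups of 4 arrays, an array was picked out when its gap to the nearest other array was large against the range of the group. Of 228 groups examined 14 met this, where about 11.4 are expected by chance.

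On SES 4 the mean of the smooth muscle contractile markers was 11.28, against 9.19 to 9.49 on the other SES arrays, and that of the cardiomyocyte markers was 8.54 against 6.04 to 6.18. The same array had BTG2 at 5.88 against 7.78 to 8.09, LAMB2 at 9.54 against 7.15 to 7.56 and RNF128 at 12.43 against 10.77 to 11.01. On ZES 1 ACTA2 was 13.50 against 15.20 to 15.51, and the mean of proteoglycans and matrix glycoproteins was 9.99 against 10.57 to 10.68. BMS 4 had a mean of 9.01 for interferon response genes, against 9.99 to 10.15, and of 7.94 for neutrophil markers, against 6.68 to 6.88. The neutrophil mean of ZES 2 was 6.64 against 9.41 to 9.73, and its complement mean was 10.73 against 9.79 to 9.95. COL3A1 was 4.92 on BMS 1 against 6.54 to 6.68, and 7.05 on ZES 4 against 6.10 to 6.23. The spike-in level of BMS 2 was 15.74 against 16.45 to 16.52.

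The first pattern weighed is the lower smooth muscle contractile signal with SES than with BMS. A lower share of smooth muscle in the dissected tissue would raise markers of other cells alike. The T and NK minus fibroblast list mean differed between SES and BMS by 2.14 (exact permutation p = 0.0286, two-sided, the smallest that 70 arrangements allow), so these lists did not move alike. This was known before the test, since both lists had been called, in opposite directions, on the same arrays. The T and NK mean with BMS, 5.11, also lay below the mean background level of 5.51. The test therefore adds no separate evidence against a lower share of smooth muscle as the sole cause. A gain of T and NK cells together with less muscle stays open. Less of the outer wall and the adjoining heart muscle in the dissected tissue stays open as well, since the cardiomyocyte list mean differed between SES and BMS by -0.80 (exact permutation p = 0.429, two-sided), with BMS arrays from 6.16 to 8.19. Array brightness remains open: ZES arrays, of similarly low spike-in level, had a mean 1.42 above SES (exact permutation p = 0.0571, two-sided), and with the spike-in level as a covariate the median moved from -1.69 to -0.61. These tests permute arrays although each pig gave 2 of them, 3 splits of 4 pigs are too few for a share under 0.05, and the exact tests of list means, 48 in number, gave adjusted p of at least 0.125, so that an effect of the stent type, which cannot be separated from the pig, stays untested beyond this.

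The second pattern is the higher signal of cytokines and chemokines with SES. Array brightness alone would leave ZES as high as SES, but the ZES mean was lower, with a difference of -1.17 (exact permutation p = 0.0286, two-sided, adjusted p = 0.125 over 48 tests) and means per pig of 8.42 and 8.48 against 9.86 and 9.39. This argues against brightness as the sole cause only if arrays are taken as exchangeable, although each pig gave 2 of them and 3 splits of 4 pigs are too few for a share under 0.05. RNA integrity may contribute: with the GAPDH difference as a covariate the median was 0.73 instead of 1.44 (list test adjusted p = 0.000949), it was 0.88 with the spike-in covariate, and the SD of the median over leaving out arrays was 0.16, so that the part left with the GAPDH covariate cannot be set above or below the middle of the former value, a criterion that was settled after this value was seen. The GAPDH difference separates SES from BMS and from ZES on every array, the EF1A difference only SES from BMS (ZES minus SES 0.67, exact permutation p = 0.171), and actin, 3' minus middle, was 2.44, 2.28 and 2.35 with BMS, SES and ZES, so that RNA integrity, on which the controls are divided, and stent type cannot be told apart for these genes, and an effect of the stent type remains an open hypothesis.

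The third pattern is the lower signal of cytosolic ribosomal proteins with both drug-eluting stents. With quantile normalization, which gives all arrays one distribution, the SES minus BMS median was 0.020 (adjusted p = 0.897). The ribosomal genes averaged 15.66 with BMS, 15.15 with SES and 15.17 with ZES, among the brightest signals of the arrays. Quantile normalization makes the brightest signals equal on all arrays, whatever the source of a difference. It therefore cannot tell array brightness from a real shift of these genes, and array brightness stays open. Among 10000 random lists of the same size and similar brightness the median of -0.50 lay at percentile 78.6 for SES, and that of -0.51 at percentile 54.6 for ZES. Those lists were drawn from all named genes within 100 ranks of brightness, the ribosomal genes included. They therefore cannot compare ribosomal genes with other genes equally bright. No biological explanation was tested.

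Other splits of the arrays were compared with the real ones. For SES against BMS 1 of 35 splits, the real one, gave 114 probe sets, and the highest of the others gave 5. That is the smallest share these splits allow, and it takes arrays as exchangeable although each pig gave 2 of them, so chance is not excluded. Over whole pigs the real split gave 114 and the highest other 0, but 3 splits are too few for a share under 0.05, and 1 of 3 gave as many. Its 14 lists were matched or exceeded in 2 of 35 splits, with 18 lists in the split that exchanges BMS 3 and SES 4, so chance cannot be excluded. For ZES against BMS the real count was 0 probe sets, which every split must reach, so that this comparison cannot inform on chance. Other splits gave up to 24. Of the 35 splits 9 gave at least the real 7 lists, up to 11, so chance cannot be excluded for the lists. For ZES against SES 2 of 35 splits gave at least 12 probe sets, and the split that exchanges SES 4 and ZES 1 gave 177, which points to a structure of the samples that crosses the stent labels. Whether these segments were exchanged or differ in the tissue dissected is not settled here. Among genes called by the real labels, SES 4 and ZES 1 lay nearer the other arrays of their own group for CXCL13 (11.01 and 4.36), RPUSD1 (11.07 and 13.10), PLAC8 (10.74 and 8.59), ARRDC4 (12.58 and 11.39) and IDH1 (10.80 and 9.49), but SES 4 lay nearer ZES for COASY (13.04) and ZES 1 nearer SES for LOC100152327 (10.55), and genes chosen by these labels cannot decide it. The GAPDH difference placed both with their own group, SES 4 at 2.98 (other SES arrays 2.33 to 3.02) and ZES 1 at 3.91 (other ZES arrays 3.44 to 3.67), while their spike-in levels, 15.60 and 14.60, each lay nearest an array of the other group. For the lists, 14 of 35 splits gave at least 7 lists, up to 14, so that chance cannot be excluded for either count. Over whole pigs 1 of 3 splits gave 12, and the highest other gave 4, again too few splits. For the F test 1 of 100 splits, the real one with 63 probe sets when the correlation is estimated on 2000 probe sets, gave as many, and the highest other gave 4. These splits too take arrays as exchangeable, so chance is not excluded. For LAD against RCA 32 of 32 exchanges within pigs gave 0, which with a real count of 0 cannot inform on chance either.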

How the results depend on the processing

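The covariates, the removal of arrays with high 28S signal, median centring of lists and the correlation estimated on arrays were added after seeing the data. Of the genes named by rule, none that passed changed direction in 16 alternatives (means per pig, arrays as independent, quantile normalization, a pseudocount and each of the 12 arrays left out), but each such call ended without SES 3. Calls ended in other alternatives too, and passed in 5 to 15 of the 16. For ZES minus SES, COASY and LOC100152327 passed in 5, IDH1 in 7, PLAC8 in 8, and RPUSD1 and CXCL13 in 15. For SES minus BMS, UPK1B passed in 6, ICAM1, GJA4 and SLA-DQA1 in 8, SH2D1A in 9, and CCL2, CCL5, CXCL13 and IER3 in 15. Single genes were not followed in the other alternatives, nor were LTB, CFP and COL4A2. The cause was not tested where a value below moved, except that fewer arrays were tested when some were left out. The alternative without a pseudocount equals the values used. The probe sets changed, SES minus BMS, probe sets changed, ZES minus SES, and probe sets changed, any stent group (F test), were 64, 4 and 47 on means per pig, 89, 6 and 29 with arrays as independent, 106, 6 and 44 with quantile normalization, and 85, 6 and 46 with median centring. They were 196, 46 and 104 with a pseudocount, 183, 48 and 108 without the filter, 19, 0 and 5 without a trend, and 678, 307 and 630 with array weights. They were 128, 26 and 76 with artery, 0, 5 and 2 with spike-in, 0, 0 and 0 with GAPDH, 26, 4 and 10 without high 28S and 8, 2 and 3 at an adjusted p under 0.01. From the arrays compared alone the first pair was 178 and 5. The counts of 0 stand beside 2408, 1686 and 2257 at an unadjusted p under 0.05 in limma. Leaving out samples gave 0 to 420 by array and 1 to 487 by pig for the first, 0 to 161 by array and 1 to 68 by pig for the second and 0 to 265 by array and 1 to 344 by pig for the third. The probe sets changed, ZES minus BMS, stayed at 0 (1510 at an unadjusted p under 0.05 in limma) except for 3 without the filter, and samples left out gave 0 to 4 by array and 0 to 79 by pig; those of LAD minus RCA stayed at 0 (1140 at an unadjusted p under 0.05).

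The list members changed, SES minus BMS, were 28 with a pseudocount, 6 without a trend, 79 with weights, 0 with spike-in, 0 with GAPDH, 8 without high 28S, 30 from the arrays compared alone and 0 to 68 by array and 0 to 61 by pig. The list members changed, ZES minus SES, were 5 with a pseudocount, 5 without the filter, 0 without a trend, 0 with GAPDH, 40 with weights, 3 with artery and 0 to 27 by array and 0 to 11 by pig. The list members changed, ZES minus BMS, stayed at 0 by array and were 0 to 7 by pig. The gene lists shifted, SES minus BMS, gene lists shifted, ZES minus BMS, and gene lists shifted, ZES minus SES, were 0, 0 and 0 with a correlation estimated on means per pig, 2, 0 and 0 with one estimated on arrays taken as independent, 5, 0 and 1 with fry, 12, 4 and 8 with quantile normalization, 7, 0 and 6 with spike-in, 10, 8 and 3 with GAPDH, 12, 9 and 8 without high 28S and 13, 4 and 9 with the mean of all probe sets of a gene, and leaving out arrays gave 12 to 16, 2 to 10 and 5 to 11. The correlation of the drug stents' differences was 0.0923 and 0.118 with BMS split by pig, where no array is shared.

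Medians of cytosolic ribosomal proteins turned to 0.020 (quantile) and 0.33 (spike-in) for SES minus BMS and 0.19 (spike-in) for ZES minus BMS, and RPS25 to 0.0099 (quantile). Medians of proteoglycans and matrix glycoproteins with GAPDH were 0.077 for SES minus BMS and -0.050 for ZES minus SES. For smooth muscle contractile markers, ZES minus BMS, it was 0.49 with spike-in and -0.45 to 0.26 with arrays left out. CXCL8, ZES minus BMS, was 0.21 with a pseudocount. Panel genes that did not pass turned sign when an array was left out. Their ranges for ZES minus BMS were COL3A1 -0.21 to 0.39, TNC -1.04 to 0.79, CXCL8 -1.35 to 1.40, SPP1 -0.33 to 0.84, FKBP1A -0.15 to 0.084 and FKBP5 -0.033 to 0.24. The range of PECAM1, SES minus BMS, was -0.0096 to 0.31. Ranges for ZES minus SES were MMP9 -0.12 to 1.76, SPP1 -0.89 to 0.27, PECAM1 -0.026 to 0.53 and VCAM1 -0.61 to 0.21. Over all alternatives, 137 list medians and 163 values of single genes lost a call and 104 values of single genes gained one. Signal over background limits folds, since 61.0% to 74.5% of probe sets per array lay above it.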

Other observations

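The artery lists in this part were tested only after the results were seen, and the other lists were planned. Several groups of vessel wall genes did not pass the list test in any comparison of stents, which does not show that they were unchanged. The 23 endothelial markers had medians of 0.28 for SES minus BMS, 0.0078 for ZES minus BMS and 0.061 for ZES minus SES (adjusted p = 0.695, 0.632 and 0.920), although GJA4 fell with SES. For the 27 monocyte and macrophage markers the medians were -0.058, -0.48 and -0.12 (adjusted p = 0.695, 0.109 and 0.411). The 16 genes of the mTOR complexes and the immunophilins that bind the drugs had medians of -0.27, -0.078 and 0.23 (adjusted p = 0.695, 0.949 and 0.653). Those of 13 TGF-beta pathway genes were 0.091, 0.040 and 0.073 (adjusted p = 0.989, 0.658 and 0.653). The complement factor gene CFP, named after its value was seen, rose by 3.00 with SES (adjusted p = 0.00549), while the complement list did not shift (adjusted p = 0.268).

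Between arteries of the same pig, lists differed where no single probe set did, and the estimated correlations named here are from the arrays with the pig as a block. MHC class II genes were lower in LAD than in RCA (median -0.81, adjusted p = 1.15e-10, and adjusted p = 0.307 with an estimated correlation), with a lower list mean in 5 of 5 pigs. Macrophage markers (median -0.48, lower in 3 of 5 pigs) and cell cycle genes (median -0.59, lower in 4 of 5) shifted down, and cardiomyocyte markers (median 1.15, higher in 4 of 5) shifted up. With an estimated correlation these gave adjusted p = 0.546 for macrophage and cardiomyocyte markers and adjusted p = 0.614 for cell cycle genes. Smooth muscle markers shifted up with a median of 0.73 (adjusted p = 0.614 with an estimated correlation), which came from 2 pigs, at 1.80 for SES 4 minus SES 3 and 2.05 for ZES 2 minus ZES 1, while the list means of the other 3 pigs differed by -0.16 to 0.059. Cytokines and chemokines shifted down in LAD (median -0.43, adjusted p = 0.0288, lower in 4 of 5 pigs), where SES had 1 LAD segment against 2 each for BMS and ZES, and every stent type had 2 from the RCA. Collagens (median 0.50, higher in 4 of 5), fibroblast markers (median 0.42, higher in 4 of 5) and ribosomal proteins (median 0.15, higher in 3 of 5) shifted up. With an estimated correlation these gave adjusted p = 0.614 for cytokines and fibroblast markers, adjusted p = 0.546 for collagens and adjusted p = 0.746 for ribosomal proteins. An interaction of artery with stent type, ZES against BMS, was called at 0 probe sets by limma, where 1380 had an unadjusted p under 0.05 and the smallest adjusted p was 0.433.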
